A study of Rattus norvegicus with 6 samples.

How the data were processed

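MicroRNA levels were measured in the infrarenal aortic wall of male Sprague-Dawley rats with 1-colour Agilent rat miRNA arrays, 1 array per rat. Per the labels, 3 rats carried an abdominal aortic aneurysm (AAA) produced with calcium chloride and collagenase, and 3 rats were controls, called both sham-operated and normal; this second group is named Normal here. Tissue was taken 28 days after the operation from rats that were 8 weeks old at the start. Total RNA was labelled with the dye Cy3, per the labels' protocols. The 6 arrays lay on 1 slide and were scanned on 1 date, per the file headers.

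The deposited scanner files hold spot intensity on a linear scale. Per the file headers they were written by Agilent Feature Extraction 10.5.1.1, whereas the submitters' processing notes name version 10.1; which of these made the values is not settled. The processed signal column is an intensity after background subtraction with no scaling between arrays, per the file headers. Flag columns give, per spot, whether it was an outlier, well above background or saturated, and, per miRNA, whether the software called it detected. The deposited value table holds log2 values. Set against the summed miRNA signal of the scanner files, each of its 6 columns had a Spearman correlation of 1 with it. The slope was between 0.972 and 1.07 on the log2 scale. Both were computed over the 156 to 171 miRNAs per array with a summed signal above 5. All 6 columns had a median of 1.94 over 395 rows, control rows included. Their quantiles were identical where the mean over the columns exceeded 1, and lower quantiles were not compared. The table was therefore read as log2 of quantile-normalized summed signal, not centred per miRNA. The step that produced it is not given in the sources used here.

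Levels were computed from the processed signal. Control spots and spots flagged as outliers (217 to 338 per array) were left out; no spot was saturated. Spots were averaged per probe and probes per miRNA on the linear scale, 5 to 20 spots per probe and 1 to 4 probes per miRNA, for 350 miRNAs, 938 probes and 7000 spots. Each array was divided by its 75th percentile over the 110 miRNAs detected on all 6 arrays. Scaled levels were then floored at 0.00863 (log2 of −6.86), the median over arrays of the 5th percentile of the scaled levels of detected miRNAs, and converted to log2. The scaling sets the reference for every change, since the arrays differed in brightness: the 75th percentile was 837, 444 and 474 in AAA replicates 1, 2 and 3 and 707, 1002 and 968 in Normal replicates 1, 2 and 3. A smaller divisor also raises the scaled level of signals near background, so dim miRNAs depend on it most. Values at the floor have no order. For a miRNA not detected on any array of a group, no fold is given, since it depends on the floor.

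The 142 miRNAs detected on all 3 arrays of at least 1 group were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (moderated test, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Files were read with the R package data.table, version 1.17.8. A set of 18 lists of miRNAs was fixed before the data were examined, as were the tests, the rule for naming miRNAs and the alternatives. The lists were smooth muscle contractile miRNAs, miRNAs tied to smooth muscle proliferation, the miR-29 family, leukocyte, red blood cell, endothelial, striated muscle, epithelial, neural and hepatocyte miRNAs, the cluster of miR-199 and miR-214, the miR-17 family clusters, the let-7 family, the imprinted Dlk1-Dio3 cluster, the miR-15 family, the clusters of miR-23, miR-24 and miR-27, the miR-30 family and the miR-181 family. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, which asks whether members shift relative to the other tested miRNAs. Camera with an estimated correlation and fry were alternatives. The numbers of miRNAs detected per array were compared with an exact permutation test, two-sided, for which 3 against 3 arrays allow no p under 0.1.

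The named miRNAs were, in each direction, up to 12 past the threshold with the largest change, filled to 5 by smallest p where fewer passed and then named as not past it. Added to these were every tested member of the contractile, proliferation, miR-29 and leukocyte lists, and the 4 members with the smallest p of each other list past its test. Of the 34 named miRNAs, 33 had the same sign of change in all probes above the floor; the exception was miR-133a. Closely related miRNAs, such as members of the let-7, miR-29 and miR-17 families, can bind each other's probes, so the share of each member in such a signal is uncertain. The array's annotation names an older rat assembly than the gene table used for names and neighbours (GRCr8), so coordinates are not printed. Of the 350 miRNAs, 346 matched a gene in that table.

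The alternatives were a 75th percentile over all miRNAs, quantile normalization, no scaling, median scaling, normexp background correction (offset 50), the software's summed signal, the value table, the brightest probe, the mean of log2 probes, a floor divided or multiplied by 2, no filter, detection on all 6 arrays, a trended and a robust eBayes, the replicate number as a block, the slide row as a covariate, a 2-fold change added to the threshold, and each array left out in turn. AAA replicate 1 and all Normal arrays lay in row 1 of the slide and AAA replicates 2 and 3 in row 2, so a fit with the row compares the groups within row 1, with 1 AAA array against 3 Normal arrays.

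The fit was tested on simulated data with the levels and spreads of the 142 tested miRNAs, 40 of them changed, in 20 simulations. It recovered 67.5% of 2-fold and 93.8% of 4-fold changes, and 4.59% of its calls were false. These simulations drew each miRNA independently, with the same spread in both groups and no floor. The real AAA arrays varied more than the Normal arrays, and some tested miRNAs lay at the floor. The recovery and false-call rates therefore need not hold for the real data. The number of arrays limits the precision of every value, and the p-values measure the spread between single rats, each with 1 array.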

Results

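The data set compared the miRNA content of the aneurysmal and the non-aneurysmal rat aorta. AAA is a localised widening of the abdominal aorta in which the elastic wall breaks down, smooth muscle is lost and inflammatory cells enter. The AAA group had 3 rats and the Normal group 3 rats, each with 1 array of 350 miRNAs. The software detected 140, 118 and 142 miRNAs in AAA replicates 1, 2 and 3 and 137, 153 and 159 in Normal replicates 1, 2 and 3. A total of 110 miRNAs were detected on all 6 arrays, 176 on none, and 142 entered the tests. The median signal of the detected miRNAs, before scaling, was 80.8, 90.5 and 97.7 intensity units in AAA replicates 1, 2 and 3 and 59.9, 65.1 and 57.8 in Normal replicates 1, 2 and 3 (exact permutation test, two-sided, p = 0.1, the smallest this design allows). Levels below are log2 of the scaled signal, and changes are AAA minus Normal, given with the standard error of the fit and 3 arrays per group. The AAA arrays varied more among themselves: the SD of their deviations from the group mean over the tested miRNAs was 0.41, 0.38 and 0.50, against 0.22, 0.30 and 0.23 on the Normal arrays.

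The first comparison asked which miRNAs differ in the aneurysm wall. Of the 142 tested, 4 were higher and 1 was lower in AAA, each with an adjusted p of 0.0438 (limma) and with every AAA array on the same side of every Normal array. miR-222, which shares its seed with miR-221 and represses the cell-cycle inhibitor Cdkn1b, rose by 2.30 ± 0.40 to a level of −4.41 ± 0.73 (SD, n = 3) in AAA. It lay at the floor on 2 of the 3 Normal arrays, so the size of this change depends on the floor. miR-146a, a feedback inhibitor of NF-kB signalling through Irak1 and Traf6, rose by 1.57 ± 0.24 (2.97-fold). miR-29b, a repressor of collagen and elastin transcripts, rose from −0.79 ± 0.21 to 0.44 ± 0.30 (SD, n = 3 each), a change of 1.22 ± 0.21 or 2.34-fold. miR-34b, a transcriptional target of Trp53, was detected on all 3 AAA arrays and on none of the Normal arrays, so the size of its rise depends on the floor and no fold is given. miR-497, a member of the miR-15 family, fell by 0.83 on the log2 scale (SE 0.14), from 0.43 ± 0.13 in Normal to −0.39 ± 0.09 in AAA (SD, n = 3 each).

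Next to these stood miRNAs that did not pass the threshold but had the smallest p-values in their direction. miR-29a, encoded next to miR-29b, had a change of 1.08 ± 0.21 (adjusted p = 0.054, limma). On the lower side, miR-195, encoded next to miR-497, had a change of −0.66 ± 0.14 and miR-100 one of −0.65 ± 0.13, both with an adjusted p of 0.054 (limma). miR-30e* had a change of −0.59 ± 0.14 (adjusted p = 0.0617, limma) and miR-335 one of −1.35 ± 0.34 (adjusted p = 0.0687, limma); miR-335 lay at the floor on all 3 AAA arrays. In all, 44 of the 142 tested miRNAs had an unadjusted p under 0.05, 27 higher and 17 lower in AAA. The groups were fully apart for 51 miRNAs (35.9%). For a miRNA taken alone, chance gives 10%. That value is no valid reference for the share of 35.9%. The tested miRNAs were chosen by detection within groups, and those on an array share its scaling. The share was not tested against chance.

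The number of calls moved with the scaling and with single arrays. The median change of the tested miRNAs was 0.17 in the main scaling and between −0.44 and 0.41 in the others, and the calls split into 4 higher and 1 lower in the main scaling, 7 and 12 with the percentile over all miRNAs, 13 and 16 after quantile normalization, 7 and 6 after median scaling, 12 and 1 after normexp, and 15 and 19 in the value table; with no scaling there were 0 calls (limma; 52 at an unadjusted p under 0.05). Calls numbered 0 when Normal replicate 1, 2 or 3 was left out, 41 without AAA replicate 1, 22 without AAA replicate 3 and 5 without AAA replicate 2, of which 1 was among the main 5. Within slide row 1, only 1 AAA array stood against 3 Normal arrays. There the changes were 1.87 for miR-222, 1.17 for miR-146a, 1.14 for miR-29b and −0.92 for miR-497. miR-34b was higher in AAA there as well, by an amount that depends on the floor. The 2 dimmest calls depended on the floor and background: with the floor multiplied by 2 the change was 1.45 for miR-222 and 0.36 for miR-34b, with normexp 0.81 and 0.55, and neither passed in those settings.

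**Figure D1:**
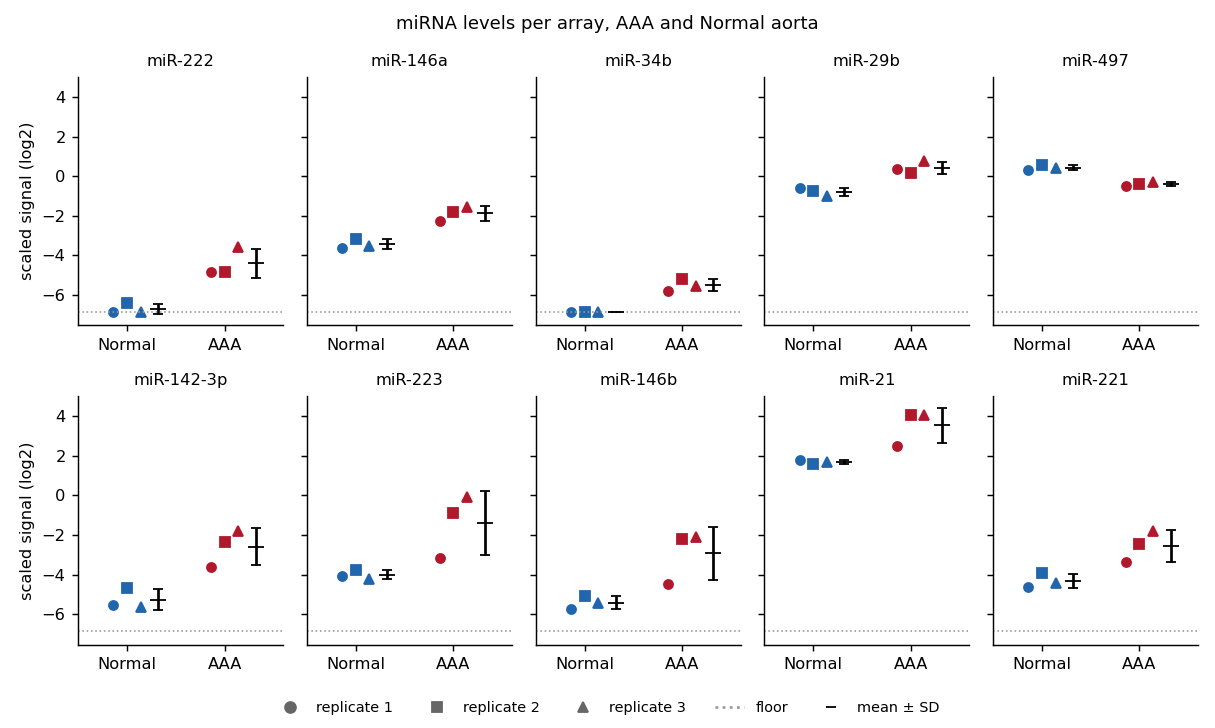
Scaled signal (log2) of 10 miRNAs on each of the 6 arrays, with 1 panel per miRNA, Normal in blue and AAA in red, symbols for the replicate number and bars for the group mean ± SD (n = 3). The AAA arrays lie above all Normal arrays for miR-222, miR-146a, miR-34b and miR-29b and below them for miR-497; in the lower row, miR-142-3p, miR-223, miR-146b, miR-21 and miR-221 lie higher in AAA, with AAA replicate 1 the lowest of the AAA arrays, and did not pass the threshold.

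Of the 14 lists that could be tested, 4 shifted between the groups, 3 upward and 1 downward (camera with a preset correlation). With a correlation estimated from the data none of the 4 passed (adjusted p from 0.41 to 0.68). Leukocyte miRNAs lay higher in AAA, with a median change of 2.03 over 6 tested members (camera, adjusted p = 0.00953, but 0.60 with an estimated correlation). All 6 had a positive change, except that miR-150 turned negative after quantile normalization, with no scaling and in the value table. miR-142-3p, expressed across blood cell lineages, had a change of 2.70 ± 0.53 (adjusted p = 0.054, limma) and miR-223, abundant in neutrophils and monocytes, one of 2.62 ± 0.80 (adjusted p = 0.10, limma). miR-146b had a change of 2.49 ± 0.69 and miR-342-3p one of 0.80 ± 0.20, while the lymphocyte miRNA miR-150 had a change of 0.60 ± 0.29 with overlapping groups. Of the members, 1 (miR-146a) passed over all tested miRNAs and 5 passed when adjusted over the list alone. The list median change was 0.88 within slide row 1, which rests on 1 AAA array. The red blood cell miRNA miR-451 moved in part with this list: its level was −1.44, −1.35 and −0.35 in AAA replicates 1, 2 and 3 and −3.36, −1.36 and −4.97 in Normal replicates 1, 2 and 3, a change of 2.18 ± 0.94 (adjusted p = 0.18, limma).

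miRNAs tied to smooth muscle proliferation shifted upward as well, with a median change of 1.78 over 7 tested members (camera, adjusted p = 0.00953, but 0.60 with an estimated correlation). All 7 changes were positive, except that miR-31 turned negative with the percentile over all miRNAs and no scaling, and miR-26a was not above 0 under any other scaling but normexp. Of these, 2 members, miR-222 and miR-146a, passed over all tested miRNAs and 5 passed when adjusted over the list alone. miR-21, among the brightest miRNAs on these arrays, had levels of 3.53 ± 0.91 in AAA and 1.69 ± 0.09 in Normal (SD, n = 3 each), a change of 1.83 ± 0.46 (adjusted p = 0.0687, limma). miR-221 had a change of 1.78 ± 0.44 (adjusted p = 0.0687, limma). miR-31 and miR-26a had changes of 0.46 ± 0.23 and 0.07 ± 0.18. The list shares 2 members, miR-146a and miR-146b, with the leukocyte list. Its median change was 0.94 within slide row 1, again from 1 AAA array.

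The miR-17 family clusters are separate groups of co-transcribed miRNAs linked to cell-cycle entry. The list shifted upward with a median change of 1.53 over 7 tested members (camera, adjusted p = 0.0304, but 0.68 with an estimated correlation). All 7 changes were positive, except that miR-93 turned negative after quantile normalization, with no scaling and in the value table, and miR-25 with no scaling. None of them passed over all tested miRNAs and 4 passed when adjusted over the list alone. The members with the smallest p were miR-19b at 2.25 ± 0.52, miR-92a at 1.79 ± 0.49, miR-20a at 1.70 ± 0.54 and miR-17 at 1.53 ± 0.52, with adjusted p from 0.0617 to 0.12 (limma). The changes were smaller for miR-106b, miR-93 and miR-25, which are encoded near each other (0.76, 0.54 and 0.54). The groups were fully apart for 3 of the 7 members. Within slide row 1, with its 1 AAA array, the adjusted p was 0.138 and the median change 0.42. Its call was also lost with fry (adjusted p = 0.13), after normexp (0.0615) and without AAA replicate 2 (adjusted p = 0.155), Normal replicate 1 (0.0543) or Normal replicate 3 (0.055).

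The let-7 family, abundant miRNAs of differentiated cells, shifted downward relative to the other tested miRNAs, with a median change of −0.34 over 10 tested members (camera, adjusted p = 0.00953, but 0.41 with an estimated correlation). For this family the estimated correlation was −0.0084, below the preset 0.01, so a larger correlation was not why the call was lost. Of its members, 8 had a negative and 2 a positive change (let-7b as well turned positive after quantile normalization), and the groups were fully apart for 7. None passed over all tested miRNAs or when adjusted over the list alone. The changes were −0.44 ± 0.12 for let-7f, −0.38 ± 0.12 for let-7d, −0.39 ± 0.13 for let-7a and −0.39 ± 0.14 for miR-98, with adjusted p from 0.0885 to 0.127 (limma). The positive members were the passenger strands let-7d* (0.70 ± 0.38), near the floor on all 3 Normal arrays, and let-7b*, which was not detected on any AAA array and lay at the floor on 2 Normal arrays, so that its change has no meaningful size. Without let-7b* the median change was −0.35. The list had adjusted p = 0.104 within slide row 1 (1 AAA array) and 0.135 without AAA replicate 3. Its median change stayed negative under every scaling, from −0.99 to −0.19, but its call was lost with the percentile over all miRNAs, quantile normalization, no scaling, median scaling and the value table (adjusted p from 0.168 to 0.418).

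**Figure D2:**
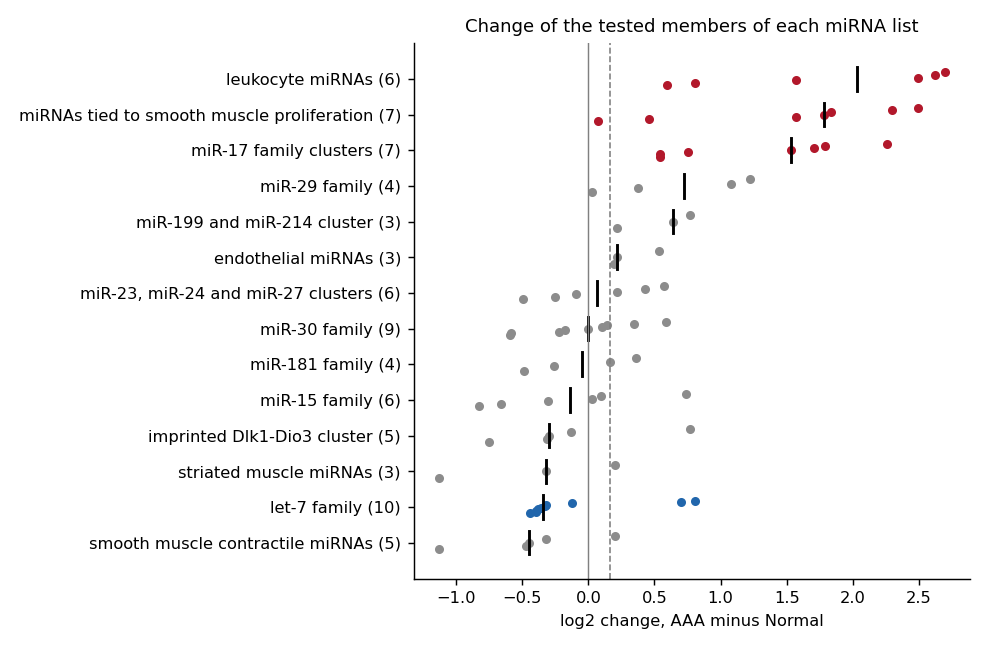
Log2 change (AAA minus Normal) of each tested member of the 14 lists with at least 3 tested members, the number in brackets, with a black line at the list median and a dashed line at the median of all tested miRNAs (0.17). Lists past the test are red where they shifted upward and blue where they shifted downward; the leukocyte list has the highest median at 2.03.

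The miR-29 family did not pass the list test (median change 0.73 over 4 tested members, camera, adjusted p = 0.158). miR-29b rose, and miR-29a, not past the threshold over all tested miRNAs in the main setting, passed it in 11 of 23 others. When adjusted over the list alone these 2 members passed, whereas miR-29c had a change of 0.38 ± 0.18 and miR-29c* one of 0.03 ± 0.25. The groups overlapped for both, and both turned negative under some scalings.

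Smooth muscle contractile miRNAs did not pass either, with a median change of −0.45 over 5 tested members (camera, adjusted p = 0.239), and none of the members passed over all tested miRNAs or over the list alone. miR-143 and miR-145, which maintain the contractile state of smooth muscle, had changes of −0.45 ± 0.31 and −0.47 ± 0.34 (adjusted p = 0.34 and 0.37, limma). Relative to the Normal mean, miR-143 was at −0.64, −0.90 and 0.19 and miR-145 at −0.76, −0.92 and 0.27 in AAA replicates 1, 2 and 3, where the SD of the Normal arrays was 0.13 and 0.10. AAA replicate 3 stood apart from the other AAA arrays in the muscle miRNAs shared with heart and skeletal muscle. Relative to the Normal mean, miR-1 was at −1.65, −1.66 and 2.35 and miR-133b at −2.41, −2.04 and 1.06 in AAA replicates 1, 2 and 3. The changes were −0.32 ± 1.13 for miR-1, −1.13 ± 0.94 for miR-133b and 0.20 ± 0.42 for miR-133a, which lay at the floor in AAA replicates 1 and 2. Without AAA replicate 3 the contractile list passed, with a median change of −0.84 (camera, adjusted p = 0.00212). Of its 5 members 3, miR-1, miR-133a and miR-133b, are all that was tested of the striated muscle list, which passed without that array as well (median change −1.66, adjusted p = 0.00843). With that array left out and an estimated correlation, chosen after the data were seen, neither list passed (adjusted p = 0.376 for both), while with fry both did (0.00528).

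**Figure D3:**
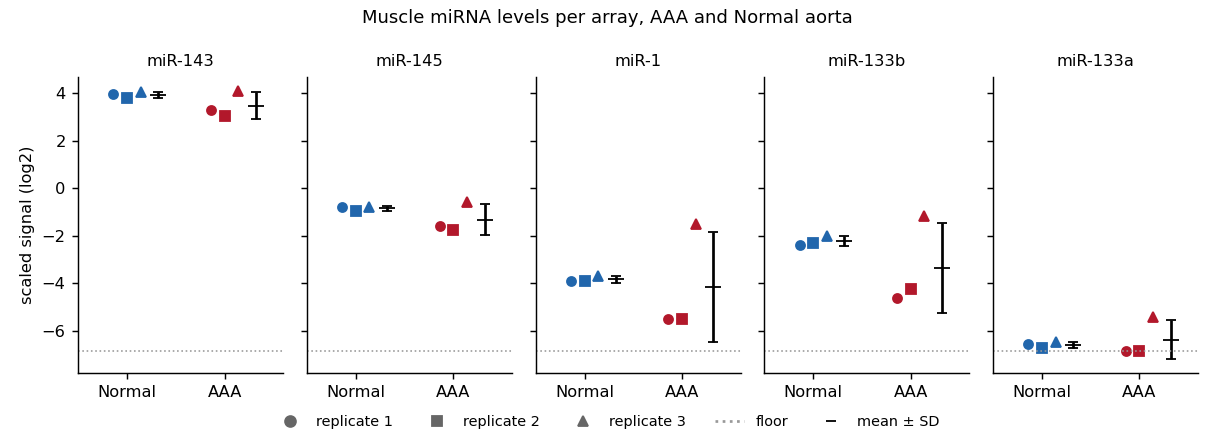
Scaled signal (log2) of 5 muscle miRNAs on each of the 6 arrays, Normal in blue and AAA in red, with symbols for the replicate number and bars for the group mean ± SD (n = 3). AAA replicate 3 lies above the Normal arrays for miR-1 and miR-133b (−1.49 and −1.16), and AAA replicates 1 and 2 lie below them.

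Of the other lists, none passed the test (camera). Adjusted p was 0.705 for endothelial miRNAs (median change 0.21), 0.577 for striated muscle miRNAs (−0.32), 0.176 for the cluster of miR-199 and miR-214 (0.64), 0.378 for the imprinted Dlk1-Dio3 cluster (−0.30) and 0.176 for the miR-15 family (−0.14), which holds miR-497 and miR-195. It was 0.598 for the clusters of miR-23, miR-24 and miR-27 (0.06, against a downward direction in the test, which is relative to the other miRNAs), 0.286 for the miR-30 family (−0.0015) and 0.679 for the miR-181 family (−0.05). Few markers of cell types foreign to the vessel wall entered the tests, so their lists had no test. Tested were 1 of 11 measured epithelial miRNAs (change 0.14), 1 of 7 neural (miR-128, 1.09), 1 of 2 red blood cell (miR-451) and 0 of 1 hepatocyte miRNAs. Detected on some array were 4 epithelial, 1 neural, 2 red blood cell and 0 hepatocyte miRNAs.

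The number of miRNAs detected per array was compared last. It was 133 ± 13.3 in AAA and 150 ± 11.4 in Normal (SD, n = 3 each). The test did not resolve this difference (exact permutation test, two-sided, p = 0.3, where the smallest p this design allows is 0.1).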

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

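The control features were not used in any comparison. The features of the control family hur_2 had a mean signal 1.34 times as high on the AAA arrays as on the Normal arrays, every AAA array above every Normal array. For the control family mr_1 the same ratio was 1.51, again with every AAA array above every Normal array. Of the 5 control families above background on all arrays these were 2; the other 3, hur_1, hur_4 and hur_6, had ratios of 1.01, 1.18 and 1.08 and did not separate the groups. Which RNA these features match is not given in the sources used here, and the smallest p an exact permutation test can give for such a difference is 0.1.

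The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For the count of miRNAs past the threshold, 1 split, the real one, gave as many as 5, and the highest of the other splits gave 0. For the count of lists, 2 splits gave as many as the real 4; the other was AAA replicates 1 and 2 with Normal replicate 2 against the rest, which also gave 4. That split follows neither the slide row nor a replicate number. The remaining splits gave 2, 2, 2, 1, 1, 1, 1 and 0 lists, so camera with the preset correlation passed lists in most groupings of these arrays.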

How the results depend on the processing

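The change of each of the 5 called miRNAs kept its sign in every setting that tested it, and none of the 34 named miRNAs or 14 lists reversed a call. Sign changes in at least 1 setting occurred for 9 named miRNAs (miR-1, miR-26a, miR-29c, miR-29c*, miR-30e*, miR-31, miR-133a, miR-150 and miR-335) and 8 list medians, none past the threshold in the main setting. Against 5 calls in the main setting, the count was 19 with the percentile over all miRNAs, 29 after quantile normalization, 13 after median scaling and 13 after normexp, 34 in the value table, 15 with the brightest probe, 9 and 10 with the floor divided and multiplied by 2, 8 with detection on all 6 arrays and 18 with a trended eBayes. It was 0 with no scaling (52 at an unadjusted p under 0.05), no filter (39), a robust eBayes (43) and the slide row as a covariate (24), all with limma; the robust fit had a smallest adjusted p of 0.0501, and the unfiltered fit tested 350 miRNAs. The cause of the other differences was not tested. Leaving out 1 array gave 0 to 41 calls, with 0 (31, 35 and 24 at an unadjusted p under 0.05) without Normal replicate 1, 2 or 3, 5 without AAA replicate 2, 22 without AAA replicate 3 and 41 without AAA replicate 1. Against 4 lists, 7 of 16 passed without a filter, 2 with the slide row, 0 with an estimated correlation, 5 with fry, which tests against no change (the miR-17 clusters lost, the miR-29 family and the miR-199 and miR-214 cluster gained), and 3 to 5 with 1 array left out. The leukocyte and proliferation lists passed in all 21 settings that enter camera with the preset correlation. The difference in miRNAs detected per array was −16.3, and −22.7 to −8.67 with 1 array left out. The share of miRNAs near background limits all counts: 24 tested miRNAs were at the floor on some array.

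Replicate numbers are shared between the groups, but nothing in the labels ties them to shared animals or days. For that reason the main fit had no block. The correlation of deviations between arrays of the same number was 0.19, 0.11 and 0.009. With 3 arrays per group, such values cannot settle whether the numbers pair the samples. AAA and Normal replicates 1 and 2 correlated best with their own number, and AAA and Normal replicate 3 with another. With the replicate number as a block (replicate block) 0 miRNAs passed (42 at an unadjusted p under 0.05, limma) and 4 lists passed.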

Other observations

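The values of neighbouring and paralogous miRNAs were chosen after the data were seen. So were the tests of residual blood and slide row for the leukocyte miRNAs. The same holds for all tests below that ask why AAA replicate 3 stood apart in the striated muscle miRNAs.

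Of the miRNAs encoded within 10000 bp of each other in the rat gene table, 44 of 56 neighbour combinations changed in the same direction. These included miR-221 with miR-222, miR-195 with miR-497, miR-29a with miR-29b, and miR-17, miR-19b, miR-20a and miR-92a. The changes include ones that did not pass the threshold, some combinations share a miRNA or a hairpin, and the count was not tested against chance. For the paralogous clusters of miR-23 and miR-27, the changes were 0.43 for miR-23a and 0.57 for miR-27a, encoded together, and −0.25 for miR-23b and −0.49 for miR-27b, encoded together elsewhere. The positive signs depend on the scaling: with no scaling the changes of miR-23a and miR-27a were −0.23 and −0.08, and miR-23a was also at −0.04 with the percentile over all miRNAs and −0.02 in the value table. Without AAA replicate 3 the change of miR-27a was 0.20. None of the 4 passed the threshold (limma, adjusted p from 0.0992 to 0.317). The difference of miR-23a minus miR-23b within an array, which dividing an array by a constant leaves as it is, was higher by 0.68 in AAA than in Normal, and that of miR-27a minus miR-27b by 1.07 (0.57 and 0.79 without AAA replicate 3; 0.38 and 1.03 in the value table), with every AAA array above every Normal array in both. The exact permutation p was 0.1 for each, the smallest this design gives, and 0.1 after adjustment over the 2. The mature forms of each paralog differ by very few bases, so part of either signal can come from the other.

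AAA replicate 3 exceeded both other AAA arrays by more than 4-fold for 5 tested miRNAs, a gap that no other array showed to the other arrays of its group for any. These were miR-1, miR-210, miR-133b, miR-327 and miR-188. miR-210, a miRNA induced by hypoxia, was at −6.68, −6.86 and −3.23 in AAA replicates 1, 2 and 3 against −5.65 ± 0.22 in Normal (SD, n = 3). miR-188 was at −3.65, −4.11 and −1.64 against −6.28 ± 0.31 in Normal, with the largest change of all tested miRNAs, 3.14 ± 0.67 (limma, adjusted p = 0.0554).

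The leukocyte miRNAs lay higher in AAA. Their list median exceeded that of all tested miRNAs by 1.87 in the main scaling (SD over the Normal arrays 0.099). Dividing an array by a constant hardly moves this excess, so settings that differ only in the divisor cannot test it. The excess was 1.67 after quantile normalization, 1.80 in the value table and 0.86 after normexp. These values argue against scaling between arrays as the whole source. Random lists matched on mean level were not drawn here, so an effect tied to signal level was not tested. Whether residual blood in proportion to red cells could be the whole source depended on the form of the test. The form given first argues against it in AAA replicates 2 and 3. There, miR-451 was at −1.35 in AAA replicate 2 and −1.36 in Normal replicate 2, where the list medians were −2.27 and −4.07. Over the members' own lines on miR-451, through all 3 or any 2 Normal arrays, the median excess was at least 1.85 and at least 2.60 prediction SE. For AAA replicate 3 the lines were extended beyond the Normal arrays (miR-451 at −0.35, against −1.36 in Normal replicate 2). Without Normal replicate 2, the lines of miR-150, miR-146a, miR-146b and miR-342-3p sloped downward, so they do not describe a rise with blood. In the same form, blood stays open for AAA replicate 1 (at least 0.75, or 1.65 SE) and for miR-150 (lowest excess −0.26). Of the 6 members, 5 were highest among the Normal arrays in replicate 2. The outcome rests on the form of the test, and all 3 forms were chosen after the values were seen. The form above, with its split by array, was adopted last, after the other 2 had given different outcomes. Of those, a line of the list median excluded blood on every AAA array (at least 0.76, SD 0.026). The spread between members (SD 0.37 to 1.30) left blood open on all. Slide row stays open: AAA replicate 1, the only AAA array in the row of the Normal arrays, lay above their mean by a median of 0.88, and 1 array cannot settle it. Entry of leukocytes into the wall may be the source, as a hypothesis, as may a change of these miRNAs within resident cells; neither was tested.

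The striated muscle miRNAs lay higher in AAA replicate 3 than in either other AAA replicate, by 3.10 at the median of 3 tested members. Slide row was argued against, since AAA replicate 2 of the same row exceeded AAA replicate 1 by at most 0.37 in the 2 members above the floor on every array. The list test could not decide on probe GC content. The median gap lay at percentile 100 of 10000 random lists matched on GC content, whose highest median was 1.71. The pattern was picked after the data were seen because these members stood out in AAA replicate 3, so a high percentile was built in. It is also too extreme by an unknown amount because the members are not independent. Taken 1 by 1, miR-1 and miR-133b exceeded each of their 15 nearest miRNAs in GC content (highest 0.86 and 1.71). This comparison carries the same selection, so it does not decide on GC content either. miR-133a (1.43) did not exceed all of its 15 nearest (highest 3.45). Skeletal or cardiac muscle in the specimen stays open. Of miR-206, miR-208 and miR-499, 0 were detected in AAA replicate 3, although 5 of the 6 measured striated muscle miRNAs were detected on some array. The level that miR-206, miR-208 and miR-499 would have in such a mixture is not known from these arrays. No biological explanation was tested, as the labels name no difference between the AAA rats.

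The let-7 family lay lower in AAA. A compression of bright signals stays open: the list median of −0.34 lay at percentile 0.66 of random lists matched on mean level, whose median was 0.083, the outcome set beforehand as evidence against it. That bound treats the members as independent, and their near-identical sequences can bind each other's probes. The correlation between members estimated from the data was −0.0084. This is 1 value for the whole list, in which positive and negative correlations can cancel, so it does not show that the members are independent. Quantile normalization, which removes a trend with level, left the list median at only −0.094 relative to that of all tested miRNAs (SD over the Normal arrays 0.067). In the value table, read as quantile-normalized, it was at −0.30. The choice to leave compression open was made after these values were seen. The scaling stays open because of the value after quantile normalization, although the list median was below that of all tested miRNAs in every scaling. A lower let-7 level in the aneurysm wall and a shift of the other miRNAs upward cannot be told apart here.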
